A study of Homo sapiens with 24 samples.

How the data were processed

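The labels give stranded RNA sequencing of poly(A) RNA, total RNA extraction with the RNeasy Plus Mini Kit of Qiagen and library preparation by Novogene. Per the submitters' processing notes, reads were counted with featureCounts on the GRCh38 build. The versions, the aligner, the gene annotation, the read length and the culture conditions are not given in the sources used here.

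The deposited values are RPKM, computed by the authors, for 16591 gene symbols in 24 libraries. Each value times the whole span of its gene in GENCODE v29, introns included, gave a whole number of reads for 100% of the nonzero values under 1000 reads, within a tolerance of 0.02 of a read. The lengths behind the values are therefore gene spans, and genes with long introns have low RPKM. A single span was found for 16544 genes and not for 47. The scaled totals behind the values ran from 23.09 M to 45.56 M reads per library (median 28.33 M), and the recovered reads summed to 93.86% to 106.68% of them. The table holds 11949 protein-coding genes, 72% of its symbols and 60% of the 19931 protein-coding symbols of GENCODE v29. Between replicates the median chi-square of a gene was 1.86 to 5.09 times that of counting error alone over the 12 groups. The mean chi-square per gene, 2.18 to 93.86, rests on few genes in some groups, with 94.9% of it in 10 genes in OVCAR8 under EPZ015666 at day 5.

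The groups, comparisons, gene lists, tests, filter, pseudocount and rule for naming genes were fixed before the data were examined. Values were transformed as log2(RPKM + 1), and a gene was tested in a line when its mean RPKM over the line's libraries was at least 1. limma 3.58.1 in R 4.3.3 was fitted per cell line with 1 mean per group, with the trend option of its empirical Bayes step, and two-sided p-values were adjusted by the Benjamini-Hochberg method within a comparison with a threshold of 0.05. The effects common to the 4 lines at day 5, their differences between lines (F test), between breast and ovarian lines and between days were contrasts of the same kind, over genes with a mean RPKM of at least 1 in each line of the contrast. The DMSO groups of day 5 and day 3 were also compared. The replicate letters were taken as labels and not as pairs.

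A set of 34 gene lists with 656 members was written from general knowledge. The table held 556 of the members, 14 of them through another symbol. A list was tested with camera at a preset correlation of 0.01 when at least 5 members were tested, and again with the correlation estimated and with fry. The z values given for lists are means of moderated t-statistics turned into normal scores, the scale on which camera compares a list with the other genes. The list p-values were adjusted over the 170 tests of the drug comparisons. The members past the threshold were counted over all genes and adjusted over the list alone. The list called histone genes in the text also holds H1F0, whose transcripts do not depend on replication.

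The named genes follow a rule. In each drug comparison the 8 largest rises and the 8 largest falls were taken among genes past the threshold with a symbol that is not clone-based, with no overlap between the groups and at least 5 RPKM in the higher group. For the common effect the 10 largest each way with the same sign in each line were taken, and for the differences between days, lines and tissues the 8 largest, all with a mean of at least 5 RPKM. Added were up to 4 members of each list with the smallest adjusted p and a fixed set of key genes (PRMT5, WDR77, CLNS1A, MDM4, E2F1, MYC, CCND1, CDKN1A, BRCA1, RBL2). The text gives a part of these. Positions are those of GENCODE v29 on GRCh38. Reads of histone genes, RPS27, U6 genes and processed copies such as BCLAF1P2, MINOS1P2, SEPT2P1, PTGES3P3, SKA2P1 and RPS24P8 may come from related copies.

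The other settings tried were a pseudocount of 0.1, no filter on low values, a mean RPKM of at least 5, median-of-ratios scaling, the replicate letter as an additive term, 1 fit over all 24 libraries, a fit of the 4 libraries compared alone, and leaving out each library in turn, where a group left with 1 library is assumed to vary like the others. Chosen after the data were seen were a fit on recovered reads (limma-voom, genes with at least 1 CPM), a correction of each library for GC content and gene span (lowess, span 0.3), the comparison of COV362 with the other 3 lines, the comparison of EPZ015666 at day 5 with DMSO at day 3, and the alternatives for the DMSO comparisons and for the overlap between comparisons.

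A simulated data set was analysed in the same way. It held 200 changed genes, with folds of 1.5 and 2. Of the tested genes with a 1.5-fold change, 70.7% (OVCAR8 day 5) to 94% (MDAMB436) were recovered in the drug comparisons and 100% in the common effect, and of those with a 2-fold change 98.9% to 100%. Between 2 and 22 unchanged genes were called per comparison. Each simulated library had the same independent spread of 0.1 log2 for all genes, besides counting error. Real genes differed in spread and many more of them changed, so these rates do not measure the error of the real calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the tables and figures.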

Results

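EPZ015666, an inhibitor of the arginine methyltransferase PRMT5, was compared with its DMSO vehicle in 4 human cancer cell lines. BT549 and MDAMB436 are breast lines and OVCAR8 and COV362 are ovarian lines. Cells had received 5 µM EPZ015666 or DMSO for 3 or 5 days in BT549 and OVCAR8, and for 5 days in COV362 and MDAMB436, before stranded poly(A) RNA sequencing. Each of the 12 groups held 2 libraries, named A and B, and each line and day had its own DMSO libraries. The labels do not say whether A and B came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical. Levels are RPKM as mean ± SD of 2 libraries, and changes are log2(RPKM + 1) of EPZ015666 minus DMSO ± SE from limma, with adjusted p-values from limma for genes and from camera for gene lists. Each named gene of a drug comparison had both drug libraries on the same side of both DMSO libraries, unless it is given as not past the threshold. The recovered read total per library ran from 23.75 M to 44.94 M reads, with a median of 27.785 M.

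In the 6 drug comparisons, 55 of 170 list tests passed an adjusted p of 0.05, 31 higher and 24 lower, across 17 lists. With an estimated correlation between genes none of the 55 calls by camera held, at adjusted p = 0.341 to 0.856, while 14 of the tests had an unadjusted p under 0.05 and fry called 99 of the 170. Fry asks whether the genes of a list move on balance in a single direction, without a comparison with other genes, and it called 48 of the 55 in the same direction.

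**Figure D1:**
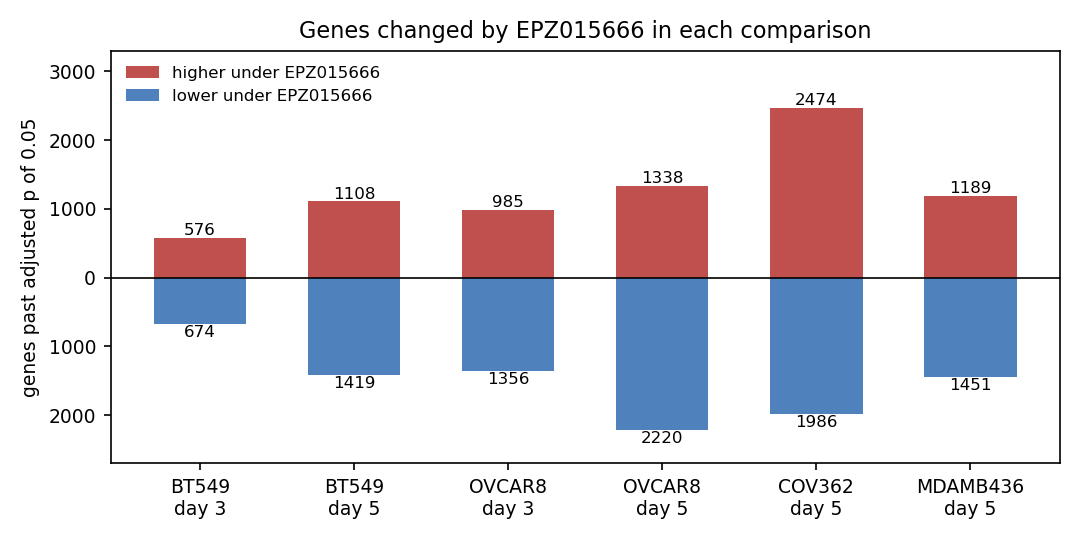
Number of genes past an adjusted p of 0.05 in each comparison of EPZ015666 with DMSO, with genes higher under the drug above 0 and genes lower below 0. COV362 had 2474 higher and 1986 lower genes, and BT549 at day 3 had 576 higher and 674 lower.

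In BT549 at day 5, AGRN, which encodes the basement membrane proteoglycan agrin, fell from 8.72 ± 0.471 to 1.49 ± 0.021 RPKM (0.171-fold, log2 change -1.96 ± 0.075, adjusted p = 1.82e-05). AGRN lies on chromosome 1 from 1020123 to 1056118 in GRCh38. The laminin genes LAMA5 and LAMB2 fell to 0.216-fold and 0.349-fold. BST2, an interferon-induced gene that tethers virus particles, fell to 0.176-fold. The surface protein gene CD24 fell from 134 ± 0.496 to 49.3 ± 2.4 RPKM. Among the rises, the metallothionein gene MT2A went from 89.1 ± 2.23 to 193 ± 2.69 RPKM (2.17-fold, log2 change 1.11 ± 0.055, adjusted p = 3.13e-05). The transferrin receptor gene TFRC rose 1.92-fold and the Notch target HES1 2.23-fold. PRPF38B, a splicing factor gene, rose 2.05-fold. RPS27 rose 2.11-fold, although reads of this ribosomal protein gene can be shared with its processed copies.

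Of 6249 genes tested in BT549 at day 5, 1108 rose and 1419 fell, of which 25 rose and 114 fell at least 2-fold. Of 8 interferon-stimulated genes 6 fell (7 adjusted over the list alone), with IFI6 at 0.294-fold and ISG15 at 0.566-fold (list median -0.592, adjusted p = 0.00204, and adjusted p = 0.518 with an estimated correlation). Of 10 antigen presentation genes 8 fell, also 8 adjusted over the list alone, with HLA-C at 0.51-fold (median -0.499, adjusted p = 0.000144, and 0.528 with an estimated correlation). Extracellular matrix and mesenchymal genes fell in 13 of 20 cases and rose in 2, the same counts adjusted over the list alone, with COL3A1 at 0.42-fold and TAGLN at 1.63-fold (median -0.294, adjusted p = 0.00528, and 0.528 with an estimated correlation). In the unfolded protein response 10 of 15 genes fell and 1 rose, the same adjusted over the list alone, with CALR at 0.583-fold, HYOU1 at 0.632-fold and EDEM1 at 1.47-fold (median -0.339, adjusted p = 0.00643, and 0.518 with an estimated correlation).

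In the same comparison 18 of 28 mitosis genes rose and 10 did not pass (20 rose adjusted over the list alone), with AURKA at 1.42-fold and BIRC5 at 1.33-fold (median 0.206, adjusted p = 1.19e-05, and 0.528 with an estimated correlation). Ribosome biogenesis genes rose in 9 of 15 cases (12 adjusted over the list alone), led by NPM1 at 1.41-fold (median 0.193, adjusted p = 0.000599, and 0.528 with an estimated correlation). In the ATR-CHK1 checkpoint list 6 of 12 genes rose and TIMELESS, which protects replication forks, fell to 0.506-fold, the same counts adjusted over the list alone (median 0.147, adjusted p = 0.0249, and 0.528 with an estimated correlation). Cholesterol genes rose in 11 of 19 cases and fell in 4 (12 and 4 adjusted over the list alone, median 0.169, adjusted p = 0.0117, and 0.738 with an estimated correlation). Of 9 NF-kB targets and cytokines 4 rose (5 adjusted over the list alone), with CXCL8 at 2.57-fold and ICAM1 at 1.74-fold (median 0.195, adjusted p = 0.0117, and 0.714 with an estimated correlation). Against DMSO of day 3, EPZ015666 at day 5 had 2 ribosome biogenesis genes higher and 2 lower (median 0.0194, camera adjusted p = 0.619). Mitosis genes were higher in 8 cases and lower in 1 (0.0911, 0.0789), and NF-kB targets in 2 and 1 (-0.0437, 0.799). The ATR-CHK1 and cholesterol medians were 0.0692 (0.506) and 0.128 (0.412). Fry did not pass these lists either, so a drug effect and a change of the vehicle with time cannot be told apart.

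SR proteins, hnRNPs and CLK kinases rose in 4 of 20 cases in BT549 at day 5, also 4 adjusted over the list alone, with HNRNPH1 at 1.75-fold (median 0.108, adjusted p = 0.0357, and 0.837 with an estimated correlation). Mitochondrially encoded genes rose in 5 of 13 cases (6 adjusted over the list alone), with MT-ND6 at 1.44-fold (median 0.174, adjusted p = 0.00798, and 0.738 with an estimated correlation). Cytosolic ribosomal protein genes fell in 11 of 33 cases and rose in 2 (10 and 2 adjusted over the list alone), with RPL10A at 0.81-fold (median -0.142, adjusted p = 0.0188, and 0.837 with an estimated correlation). A correction for GC content and gene span took the SR median to 0.023 (quartiles -0.0404 and 0.132, against 0.0125 and 0.17 before) and the ATR-CHK1 median to 0.0949 (-0.0275 and 0.148, against 0.0831 and 0.186), which ended both calls (adjusted p = 0.499 and 0.345). The ribosomal and mitochondrial calls also ended (0.0658 each), with medians still at -0.11 (quartiles -0.165 and -0.0225, against -0.206 and -0.0984) and 0.159 (0.1 and 0.35, against 0.0958 and 0.371). Fry ended the SR and ribosomal calls (0.0652 and 0.115) and a fit on recovered reads ended the ATR-CHK1 call (0.0614, at a median of 0.178). Leaving out DMSO day 5 replicate B or EPZ015666 day 5 replicate A ended the SR call (0.0655 and 0.077, at medians of 0.09 and 0.0688). Leaving out DMSO day 5 replicate A or EPZ015666 day 5 replicate A ended the ribosomal call (0.086 and 0.0761, at -0.128 and -0.117). The 2527 genes past the threshold became 1658, 1501, 1381 and 1560 without DMSO day 5 replicate A, DMSO day 5 replicate B, EPZ015666 day 5 replicate A and EPZ015666 day 5 replicate B. The fit on recovered reads called 5021 of 11735 genes. For EPZ015666 at day 5 against DMSO of day 3 the SR and ribosomal medians were -0.00674 and 0.0413 (camera adjusted p = 0.799 and 0.125). The mitochondrial median stayed at 0.209 (0.0034). The unfolded protein response and extracellular matrix medians were -0.183 and -0.138 there, past the threshold with fry (0.0033 and 0.00628) but not with camera (0.0748 and 0.203).

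In BT549 at day 3, AGRN was already lower, at 1.9 ± 0.238 RPKM against 6.76 ± 0.568 (0.281-fold, log2 change -1.42 ± 0.075, adjusted p = 0.00027). IFI6, an interferon-induced mitochondrial protein gene on chromosome 1 from 27666061 to 27672218, fell from 30.9 ± 0.208 to 11.1 ± 0.186 RPKM (0.358-fold, adjusted p = 7.61e-05). The long non-coding RNA NEAT1 fell to 0.429-fold. The linker histone gene H1F0 fell from 135 ± 3.49 to 70.9 ± 5.44 RPKM. PRPF38B rose from 9.45 ± 0.643 to 19.8 ± 2.05 RPKM (2.1-fold, log2 change 0.99 ± 0.077, adjusted p = 0.000662). The histone gene HIST2H2BE rose 2.15-fold, in a family whose members share sequence.

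Of 6249 genes in BT549 at day 3, 576 rose and 674 fell. Cholesterol genes rose in 12 of 19 cases and fell in 0 by limma (13 rose adjusted over the list alone), with HMGCS1 at 1.63-fold and MVK at 1.84-fold (median 0.289, adjusted p = 3.44e-06, and 0.528 with an estimated correlation). Interferon-stimulated genes fell in 6 of 8 cases (8 adjusted over the list alone), with IRF7 at 0.482-fold (median -0.466, adjusted p = 3.44e-06, and 0.343 with an estimated correlation). Antigen presentation genes fell in 6 of 10 cases, also 6 adjusted over the list alone, with PSMB8 at 0.689-fold (median -0.287, adjusted p = 0.000184, and 0.528 with an estimated correlation). NF-kB targets and cytokines rose in 5 of 9 cases (8 adjusted over the list alone), with CXCL8 at 2.7-fold (median 0.316, adjusted p = 0.00234, and 0.562 with an estimated correlation). DNA replication genes fell in 8 of 24 cases and rose in 1 (10 and 2 adjusted over the list alone), with MCM4 at 0.774-fold and CDC6 at 0.772-fold (median -0.116, adjusted p = 0.00801, and 0.714 with an estimated correlation).

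Histone genes rose in 6 of 9 cases in BT549 at day 3 and fell in 1, H1F0 (7 and 1 adjusted over the list alone), with HIST1H2BD at 2.16-fold (median 0.53, adjusted p = 0.00866, and 0.518 with an estimated correlation). Hypoxia and glycolysis genes rose in 5 of 15 cases and fell in 1 (6 and 1 adjusted over the list alone), with NDRG1 at 1.51-fold (median 0.0877, adjusted p = 0.0284, and 0.528 with an estimated correlation). Of 13 ATF4 targets 4 rose and 1 fell, the same adjusted over the list alone, with CHAC1 at 1.76-fold (median 0.135, adjusted p = 0.032, and 0.714 with an estimated correlation). Of 33 cytosolic ribosomal protein genes 1 rose, also adjusted over the list alone, and that was RPS27 at 2.06-fold (median 0.0887, adjusted p = 0.036, and 0.856 with an estimated correlation). Replicate A of EPZ015666 at day 3 held 1.39% of its reads in 4 genes of the ribosomal RNA locus on 21p, against a median of 0.285% over the 24 libraries. Without this library the ATF4 and hypoxia calls ended (adjusted p = 0.145 and 0.0627), although the medians were 0.114 and 0.118, and the ribosomal median was 0.149. Without DMSO day 3 replicate A the ATF4 call ended at a median of 0.0679 (0.144), and without DMSO day 3 replicate B the hypoxia call at 0.0664 (0.158). The ribosomal call ended with fry (0.2), without DMSO day 3 replicate A (median 0.0637, adjusted p = 0.41) and without EPZ015666 day 3 replicate B (median 0.0157, adjusted p = 0.617). Without the latter the NF-kB median was 0.185, still past the threshold. The 1250 genes past the threshold became 615 without EPZ015666 day 3 replicate B, 826 without EPZ015666 day 5 replicate A and 826 without EPZ015666 day 5 replicate B, 548 in a fit of the 4 libraries alone, 2487 in 1 fit of all 24 libraries, 2026 after the GC and span correction and 3021 of 11735 in the fit on recovered reads.

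In OVCAR8 at day 5, MSLN, which encodes the surface protein mesothelin, fell from 47.3 ± 0.873 to 6.83 ± 0.117 RPKM (0.144-fold, log2 change -2.63 ± 0.055, adjusted p = 1.52e-05). MSLN lies on chromosome 16 from 760762 to 768865. ACADVL, for a mitochondrial fatty acid dehydrogenase, fell from 26.2 ± 0.353 to 6.4 ± 0.61 RPKM (0.244-fold). NAPRT, for an enzyme of NAD synthesis, fell to 0.227-fold and AGRN to 0.245-fold. PSAT1, a serine synthesis gene, rose from 4.17 ± 0.128 to 8.79 ± 0.21 RPKM (2.11-fold, log2 change 0.92 ± 0.04, adjusted p = 3.34e-05). DDIT4, a stress-induced inhibitor of mTORC1 signalling, rose 1.99-fold. CTGF, a target of YAP and TGF-beta, rose 1.91-fold. The U6 gene RNU6-9 (3.01-fold, adjusted p = 0.0404) and BCLAF1P2 (1.94-fold) have near-identical copies, so their reads cannot be placed with certainty.

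Of 6328 genes in OVCAR8 at day 5, 1338 rose and 2220 fell, so 37.6% of the genes past the threshold rose, against 49.9% after median-of-ratios scaling (1780 rose and 1784 fell). ATF4 targets rose in 11 of 13 cases and fell in 1, the same adjusted over the list alone, with PHGDH at 1.57-fold, SLC3A2 at 1.58-fold and PYCR1 at 0.688-fold (median 0.556, adjusted p = 1.1e-05, and 0.341 with an estimated correlation). Cholesterol genes rose in 13 of 18 cases and fell in 3, the same adjusted over the list alone, with HMGCS1 at 1.7-fold (median 0.251, adjusted p = 0.000235, and 0.343 with an estimated correlation). SR proteins, hnRNPs and CLK kinases rose in 13 of 21 cases, also 13 adjusted over the list alone, with HNRNPM at 1.57-fold and HNRNPH1 at 1.73-fold (median 0.173, adjusted p = 0.000774, and 0.518 with an estimated correlation). Interferon-stimulated genes fell in 9 of 10 cases, also 9 adjusted over the list alone, with IFI44 at 0.23-fold and ISG15 at 0.342-fold (median -0.306, adjusted p = 0.00914, and 0.528 with an estimated correlation). Antigen presentation genes fell in 7 of 10 cases and rose in 1, the same adjusted over the list alone, with HLA-E at 0.561-fold and HLA-F at 0.363-fold (median -0.489, adjusted p = 0.0179, and 0.528 with an estimated correlation).

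Cytosolic ribosomal protein genes fell in 32 of 33 cases in OVCAR8 at day 5, and RPS27 rose 2.45-fold, the same counts adjusted over the list alone (median -0.296, adjusted p = 2.93e-05, and 0.738 with an estimated correlation). Histone genes rose in 4 of 7 cases and fell in 1 (5 and 1 adjusted over the list alone), with HIST2H2BE at 2.7-fold and HIST1H1C at 1.75-fold (median 0.763, adjusted p = 0.0318, and 0.714 with an estimated correlation). Mitochondrially encoded genes rose in 6 of 13 cases (5 adjusted over the list alone), with MT-ND2 at 1.76-fold (median 0.407, adjusted p = 0.0105, and 0.837 with an estimated correlation). EPZ015666 replicate B held 4.54% of its reads in the 4 genes of the ribosomal RNA locus and 9.93% in its top 10 genes, against 0.23% and 6.71% in replicate A, and without replicate B the mitochondrial median fell to 0.216 and the call ended (adjusted p = 0.0602), as it did with fry (0.142). The histone call ended with median-of-ratios scaling (0.0874) and with the GC and span correction (0.0536), but its median did not fall, at 0.804 (quartiles 0.684 and 1.01) and 0.908 (0.812 and 1.14) against quartiles of 0.638 and 0.96 before. The mean z of the other genes moved from -0.56 to -0.03 and -0.01, and camera compares the list with them. The fit on recovered reads called 6952 of 12423 genes. Against DMSO of day 3, ATF4, cholesterol and histone medians of EPZ015666 at day 5 stayed at 0.427, 0.303 and 0.89. Ribosomal protein genes, however, were lower in 5 cases and higher in 1 (median -0.059, camera adjusted p = 0.5). The SR list had 3 genes higher and 3 lower (-0.0239, 0.835), and the mitochondrial list 1 higher (0.0929, 0.409). Fry did not pass these last lists either. For them a drug effect and a change of the vehicle with time cannot be told apart.

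In OVCAR8 at day 3, MSLN fell from 31.4 ± 0.788 to 5.96 ± 0.548 RPKM (0.19-fold, log2 change -2.22 ± 0.055, adjusted p = 5.25e-05). ACADVL fell to 0.287-fold. TYMP, for thymidine phosphorylase, fell to 0.342-fold, and the growth factor receptor gene FGFR4 to 0.426-fold. CREBZF, which encodes a bZIP transcription factor, rose from 2.43 ± 0.0368 to 5.52 ± 0.105 RPKM (2.27-fold, log2 change 0.92 ± 0.025, adjusted p = 5.25e-05). The hypoxia-induced peptide gene ADM rose 1.69-fold and the small nucleolar RNA host gene SNHG19 rose 1.8-fold.

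Of 6328 genes in OVCAR8 at day 3, 985 rose and 1356 fell. ATF4 targets rose in 11 of 13 cases and fell in 1, the same adjusted over the list alone, with STC2 at 1.67-fold and PSAT1 at 1.6-fold (median 0.454, adjusted p = 5.72e-06, and 0.341 with an estimated correlation). Cholesterol genes rose in 12 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone), with SQLE at 1.5-fold (median 0.272, adjusted p = 6.72e-06, and 0.341 with an estimated correlation). SR proteins, hnRNPs and CLK kinases rose in 14 of 21 cases, also 14 adjusted over the list alone, with TRA2B at 1.23-fold (median 0.142, adjusted p = 5.5e-05, and 0.354 with an estimated correlation). In the unfolded protein response 10 of 15 genes fell and 2 rose, the same adjusted over the list alone, with CALR at 0.668-fold and HSPA5, the main chaperone of the endoplasmic reticulum, at 0.736-fold (median -0.29, adjusted p = 0.00643, and 0.528 with an estimated correlation). Interferon-stimulated genes fell in 8 of 10 cases, also 8 adjusted over the list alone, with IFI44 at 0.232-fold (median -0.258, adjusted p = 0.000627, and 0.518 with an estimated correlation). Antigen presentation genes fell in 8 of 10 cases and rose in 1, the same adjusted over the list alone, with HLA-E at 0.65-fold (median -0.444, adjusted p = 0.00271, and 0.518 with an estimated correlation).

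Mitochondrially encoded genes rose in 5 of 13 cases in OVCAR8 at day 3 (6 adjusted over the list alone), with MT-ND2 at 1.51-fold (median 0.326, adjusted p = 0.0174, and 0.837 with an estimated correlation). Of 16 extracellular matrix and mesenchymal genes 8 fell and 1 rose (8 and 2 adjusted over the list alone), with COL6A2 at 0.468-fold and CTGF at 1.55-fold (median -0.134, adjusted p = 0.0444, and 0.738 with an estimated correlation). The mitochondrial call ended with fry (adjusted p = 0.194) and without EPZ015666 day 3 replicate A (0.142, at a median of 0.229). It also ended with the GC and span correction (0.0531), at a median of 0.33 (quartiles 0.131 and 0.493, against 0.126 and 0.482), while the mean z of the other genes moved from -0.22 to -0.01. The extracellular matrix call ended in the fit on recovered reads (0.102, at a median of -0.0908) and without DMSO day 5 replicate B (0.0506), EPZ015666 day 5 replicate A (0.0523), EPZ015666 day 5 replicate B (0.0542) or EPZ015666 day 3 replicate B (0.0773), at medians of -0.134 and, for the last, -0.119. The 2341 genes past the threshold became 1439 without DMSO day 3 replicate A and 1383 without DMSO day 3 replicate B, and the fit on recovered reads called 4817 of 12423 genes.

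In COV362 at day 5, CXCL8, which encodes the neutrophil attractant interleukin-8, rose from 4.1 ± 0.0274 to 21.4 ± 0.753 RPKM (5.21-fold, log2 change 2.13 ± 0.033, adjusted p = 9.69e-05). CXCL8 lies on chromosome 4 from 73740506 to 73743716. TGM2, for a protein cross-linking enzyme, rose from 7.3 ± 0.0507 to 29.2 ± 0.302 RPKM. CXCL5 rose 5.58-fold, the BMP inhibitor gene NOG rose 3.54-fold and the Wnt inhibitor gene DKK1 rose 3.43-fold. IFI6 fell from 26.9 ± 2.13 to 3.01 ± 0.151 RPKM (0.112-fold, log2 change -2.8 ± 0.063, adjusted p = 9.97e-05). IFI27 fell to 0.22-fold and the mitochondrial carrier gene UCP2 fell to 0.3-fold. MSLN fell to 0.213-fold. MUC1, which encodes a cell surface mucin, fell to 0.326-fold. MIR3648-2 (4.76-fold, adjusted p = 0.00129) and MIR3687-2 (3.37-fold, adjusted p = 0.0118) have copies in the ribosomal RNA locus, so their reads cannot be placed with certainty.

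**Figure D2:**
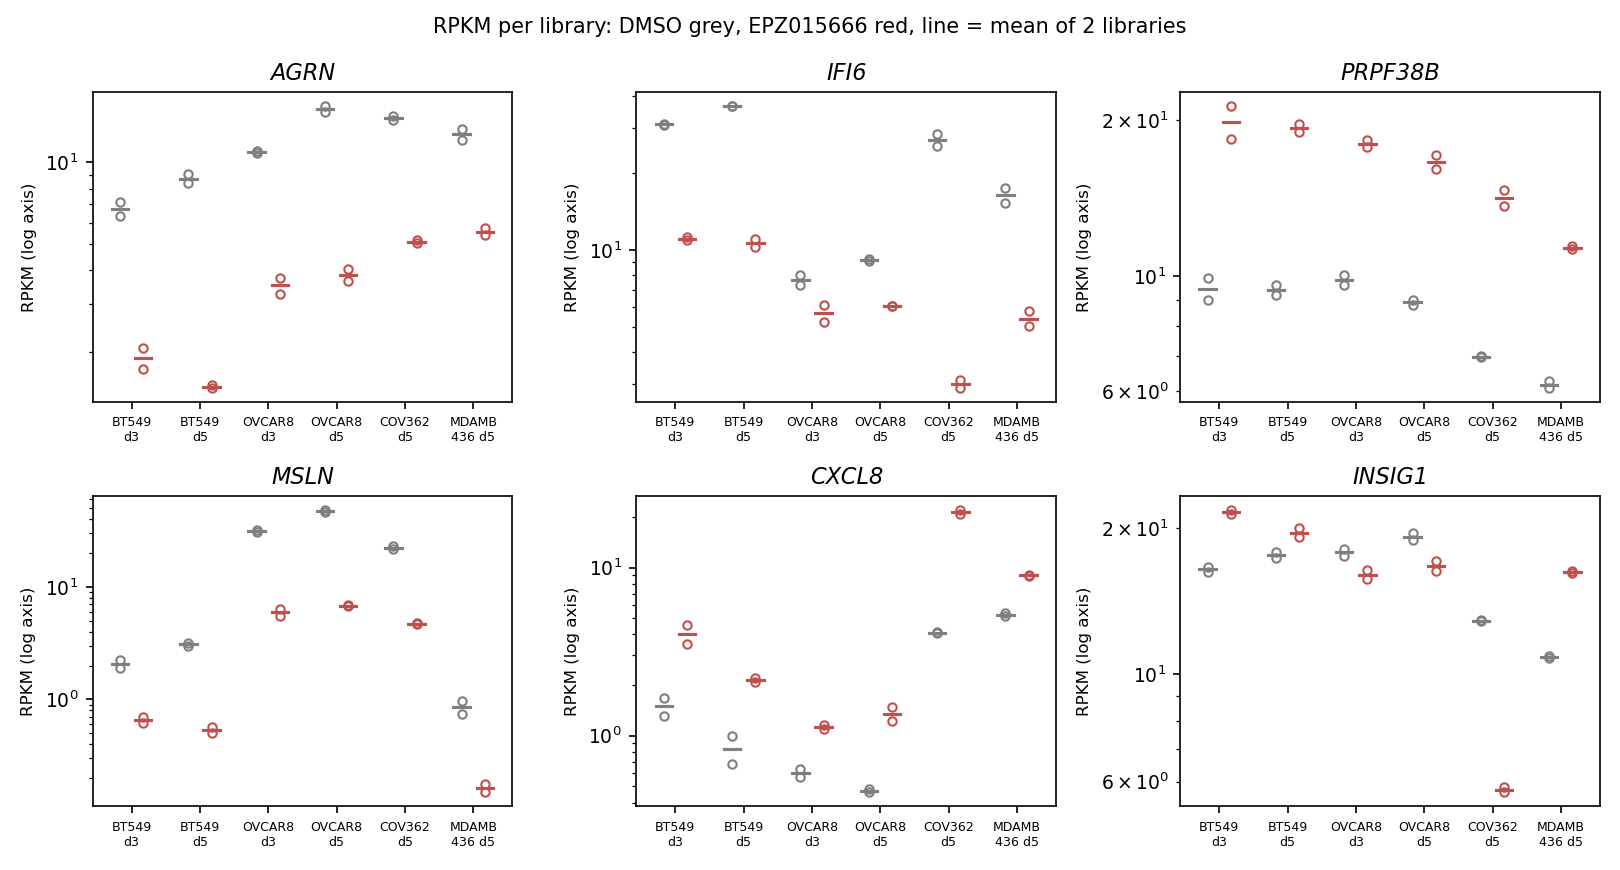
RPKM per library on a log axis for 6 genes, DMSO in grey and EPZ015666 in red, with the mean of 2 libraries as a bar. AGRN, IFI6 and MSLN were lower under EPZ015666 and PRPF38B and CXCL8 higher at each line and day, while INSIG1 was higher in BT549 and MDAMB436 and lower in OVCAR8 and COV362.

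Of 6300 genes in COV362, 2474 rose and 1986 fell, 145 and 162 of them at least 2-fold. All 16 interferon-stimulated genes tested fell, also 16 adjusted over the list alone, with OASL at 0.188-fold and ISG15 at 0.337-fold (median -1.2, adjusted p = 2.79e-08, and 0.528 with an estimated correlation). All 9 antigen presentation genes tested fell, also 9 adjusted over the list alone, with PSMB8 at 0.554-fold and B2M, the shared light chain of MHC class I, at 0.67-fold (median -0.462, adjusted p = 0.000521, and 0.528 with an estimated correlation). All 10 NF-kB targets and cytokines tested rose, also 10 adjusted over the list alone, with CCL2 at 2.58-fold and IL6 at 8.49-fold (median 0.675, adjusted p = 0.000453, and 0.577 with an estimated correlation). Cholesterol genes fell in 16 of 19 cases and rose in 1, the same adjusted over the list alone, with INSIG1 at 0.448-fold and MVD at 0.425-fold (median -0.286, adjusted p = 5.5e-05, and 0.518 with an estimated correlation).

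In COV362, ATF4 targets rose in 11 of 14 cases and fell in 2, the same adjusted over the list alone, with STC2 at 2.19-fold and TRIB3 at 2.33-fold (median 0.464, adjusted p = 0.0249, and 0.714 with an estimated correlation). The unfolded protein response list rose in 13 of 15 cases and fell in 1, the same adjusted over the list alone, with HERPUD1 at 1.71-fold (median 0.277, adjusted p = 0.00962, and 0.528 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 9 cases and fell in 1, the same adjusted over the list alone, with NDRG1 at 2.45-fold and VEGFA at 1.83-fold (median 0.488, adjusted p = 0.0124, and 0.528 with an estimated correlation). Ribosome biogenesis genes rose in 13 of 17 cases and fell in 1, the same adjusted over the list alone, with RRP9 at 1.93-fold (median 0.306, adjusted p = 0.0128, and 0.823 with an estimated correlation). Cytosolic ribosomal protein genes fell in 28 of 33 cases and rose in 1 (30 and 1 adjusted over the list alone), with RPL10A at 0.616-fold (median -0.25, adjusted p = 6.72e-06, and 0.738 with an estimated correlation). Mitochondrially encoded genes rose in 9 of 13 cases, also 9 adjusted over the list alone, with MT-ND5 at 1.58-fold (median 0.569, adjusted p = 0.0179, and 0.815 with an estimated correlation). These genes took 1.62% and 1.71% of the reads in the EPZ015666 libraries against 1.38% and 1.25% in the DMSO libraries. The fit on recovered reads called 8810 of 12466 genes, 4295 higher and 4515 lower, so the larger number of rises did not hold there.

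In MDAMB436 at day 5, the histone gene HIST2H2BE rose from 1.5 ± 0.243 to 5.25 ± 0.166 RPKM (3.49-fold, log2 change 1.32 ± 0.073, adjusted p = 0.00215). HIST2H2AA4, which has a near-identical copy, rose 2.47-fold. IGFN1, for an immunoglobulin-like and fibronectin domain protein, rose 2.2-fold. IFI6 fell from 16.3 ± 1.53 to 5.4 ± 0.521 RPKM (0.331-fold, log2 change -1.44 ± 0.086, adjusted p = 0.00223). ACP2, a lysosomal phosphatase gene, fell to 0.323-fold, LAMA5 to 0.36-fold, NAPRT to 0.394-fold and AGRN to 0.437-fold. The copies RNU6-173P (4.31-fold, adjusted p = 0.0173) and MINOS1P2 (2.4-fold, adjusted p = 0.0034) rose with the same uncertainty about the source of their reads.

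Of 6251 genes in MDAMB436, 1189 rose and 1451 fell. Cholesterol genes rose in 15 of 19 cases (16 adjusted over the list alone), with HMGCS1 at 1.83-fold, SC5D at 1.72-fold and INSIG1 at 1.5-fold (median 0.36, adjusted p = 1.2e-06, and 0.528 with an estimated correlation). Interferon-stimulated genes fell in 8 of 11 cases (9 adjusted over the list alone), with OASL at 0.633-fold (median -0.318, adjusted p = 0.00143, and 0.528 with an estimated correlation). Antigen presentation genes fell in 6 of 8 cases, also 6 adjusted over the list alone, with HLA-B at 0.605-fold (median -0.418, adjusted p = 0.00557, and 0.528 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 13 cases (11 adjusted over the list alone), with MT-ND3 at 1.48-fold (median 0.329, adjusted p = 5.87e-05, and 0.518 with an estimated correlation). They took 3.03% and 3% of the reads in the EPZ015666 libraries against 2.51% and 2.5% in the DMSO libraries. Histone genes rose in 4 of 6 cases and fell in 1, the same adjusted over the list alone (median 0.634, adjusted p = 0.0444, and 0.562 with an estimated correlation).

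Heat shock genes fell in 7 of 11 cases in MDAMB436 and rose in 1, the same adjusted over the list alone, with HSP90AB1 at 0.79-fold and HSPB1 at 0.711-fold (median -0.177, adjusted p = 0.0357, and 0.754 with an estimated correlation). Mitosis genes fell in 10 of 25 cases and rose in 1 (11 and 1 adjusted over the list alone), with KIF20A at 0.659-fold and AURKB at 0.803-fold (median -0.104, adjusted p = 0.0357, and 0.837 with an estimated correlation). Cytosolic ribosomal protein genes fell in 12 of 33 cases and rose in 1 (15 and 1 adjusted over the list alone), with RPS2 at 0.758-fold (median -0.119, adjusted p = 0.00804, and 0.837 with an estimated correlation). The heat shock call ended with the replicate letter as a term (adjusted p = 0.0544) and without DMSO replicate B (0.0795) or EPZ015666 replicate A (0.0634), at medians of -0.177, -0.186 and -0.173. The mitosis call ended with fry (0.0841) and without DMSO replicate B (0.162, at a median of -0.0761) or EPZ015666 replicate A (0.0954, at -0.0827). The ribosomal call ended with fry (0.121) and without DMSO replicate A (0.0528, at -0.0901). The histone call ended with median-of-ratios scaling (0.0553) and the GC and span correction (0.116), but its median did not fall, at 0.645 (quartiles 0.227 and 0.888) and 0.719 (0.199 and 0.969) against quartiles of 0.216 and 0.877 before. The mean z of the other genes moved from -0.13 to -0.03 and 0.01, and that of the list from 2.21 to 2.24 and 2.06. The 2640 genes past the threshold became 1323 without EPZ015666 replicate A and 1363 without EPZ015666 replicate B, and the fit on recovered reads called 5826 of 12025 genes.

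**Figure D3:**
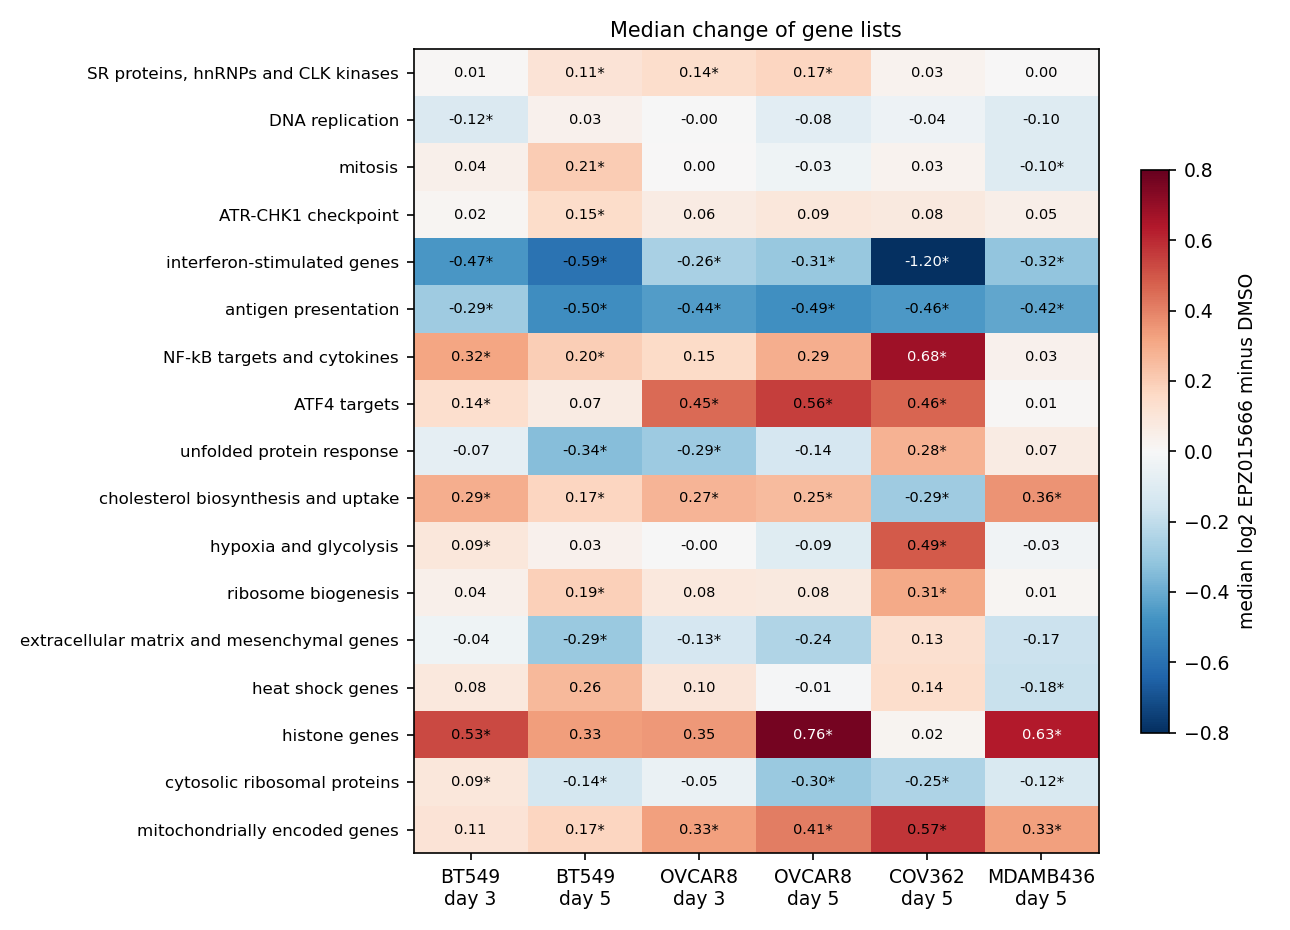
Median log2 change, EPZ015666 minus DMSO, of each gene list that passed in at least 1 comparison, with lists down the side and comparisons along the bottom, red for higher, blue for lower and * for an adjusted p under 0.05 by camera. Interferon-stimulated genes had negative medians in 6 of 6 comparisons, from -0.258 to -1.2, and cholesterol genes had positive medians except for -0.286 in COV362.

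**Figure D4:**
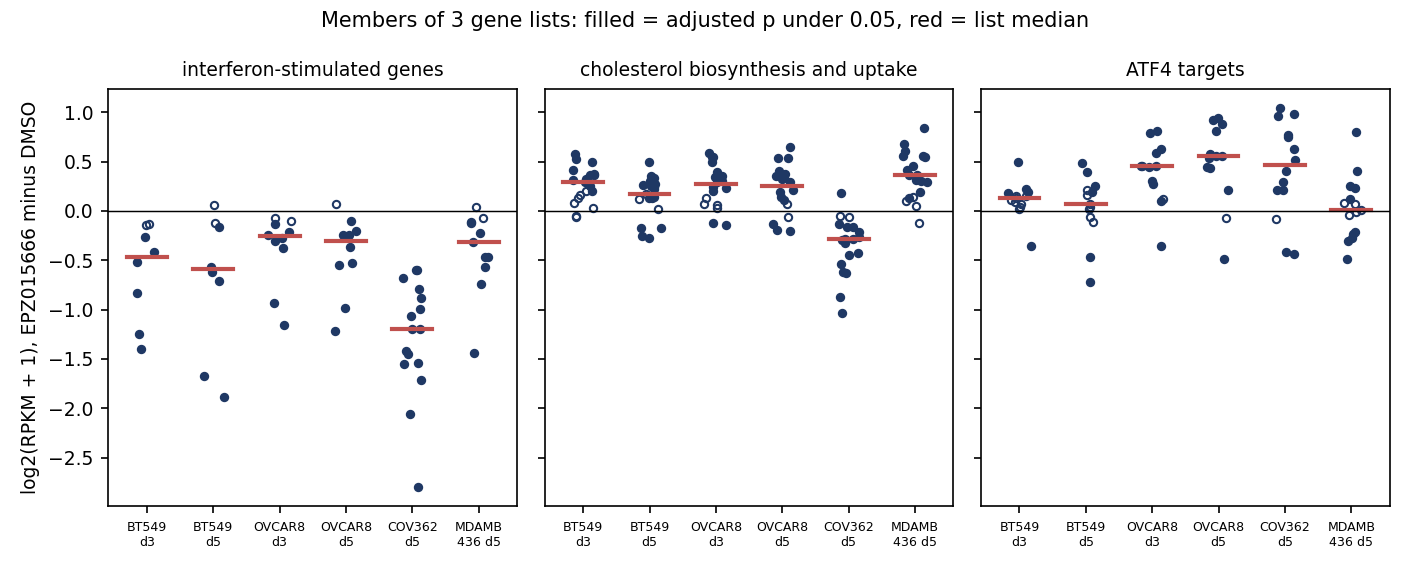
Change in log2(RPKM + 1), EPZ015666 minus DMSO, of each member of the interferon, cholesterol and ATF4 lists in each comparison, filled where the gene passed an adjusted p of 0.05, with the list median in red. All 16 interferon members in COV362 lie below 0, down to -2.8 for IFI6.

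The drug target PRMT5 rose 1.32-fold in BT549 at day 5 (adjusted p = 0.00601), 1.09-fold and 1.24-fold in OVCAR8 at day 5 and day 3 (0.0138 and 0.000722), 1.42-fold in COV362 (0.0055) and 1.17-fold in MDAMB436 (0.0242). In BT549 at day 3 its change of 1.02-fold did not pass (0.77). WDR77, the partner of PRMT5 in the methylosome, fell to 0.742-fold in MDAMB436 (adjusted p = 0.0258) and rose 1.23-fold in BT549 at day 5 (0.0246), 1.16-fold in OVCAR8 at day 5 (0.0489) and 1.09-fold in COV362 (0.036). MYC fell in OVCAR8 to 0.702-fold at day 3 and 0.763-fold at day 5, and rose 1.33-fold in COV362 (adjusted p = 0.000697, 0.000853 and 0.000381). CDKN1A, the cell cycle inhibitor p21, rose 1.69-fold in COV362, 1.45-fold in MDAMB436 and 1.24-fold in BT549 at day 3. It fell to 0.833-fold in OVCAR8 at day 5 and 0.89-fold at day 3. CCND1 fell to 0.742-fold and 0.899-fold in OVCAR8 at day 3 and day 5. It rose 1.23-fold in MDAMB436, 1.18-fold in COV362 and 1.21-fold in BT549 at day 5. E2F1 rose 1.19-fold in COV362 (adjusted p = 0.00213). CLNS1A, another methylosome gene, fell to 0.892-fold in OVCAR8 at day 5 (adjusted p = 0.0469). MDM4, a p53 regulator whose splicing depends on PRMT5, rose 1.16-fold in MDAMB436 (adjusted p = 0.0402). It was below the RPKM filter in the other lines, where the fit on recovered reads gave MDM4 log2 changes of 0.77 in BT549 and 0.67 in OVCAR8 at day 5 (adjusted p = 1.15e-05 and 1e-05). At day 3 it gave -0.01 in BT549 and 0.14 in OVCAR8, and in COV362 at day 5 it gave -0.11, none of them past the threshold (0.932, 0.244 and 0.134). For RBL2, also below the filter in COV362, that fit gave -0.72 (adjusted p = 1.17e-09). BRCA1 lay below the filter in each line, from 0.149 to 0.712 RPKM. RPKM here divides by the whole gene span, so this does not show that BRCA1 had few reads. MTAP, CDKN2A and ST7 were not analysed here.

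Of the 29 lists tested, 12 passed in none of the drug comparisons by camera. The PRMT family and methylosome had medians from -0.0882 to 0.0527 (lowest adjusted p = 0.266), and p53 target genes from -0.0154 to 0.134 (0.284) with AEN at 2.1-fold, GDF15 at 4.02-fold and BTG2 at 0.293-fold in COV362. Sm proteins and snRNP assembly genes rose in 10 of 16 cases in COV362, also 10 adjusted over the list alone (median 0.144, adjusted p = 0.0532). Fanconi anaemia genes fell in 4 of 5 cases there, also 4 adjusted over the list alone (median -0.247, adjusted p = 0.0577). Epithelial genes fell in 5 of 6 cases in OVCAR8 at day 5 (median -0.273, adjusted p = 0.079), and G1/S regulators fell in 7 of 11 there (median -0.16, adjusted p = 0.112). The lowest adjusted p was 0.29 for end joining, 0.59 for base excision repair and PARPs, 0.639 for the BCL2 family, 0.203 for immediate early genes, 0.418 for NRF2 targets and iron handling, and 0.42 for methionine and polyamine metabolism. A further 5 lists had under 5 tested members. Of 14 leukocyte markers 2 were in the table, with CD14 at up to 4.93 RPKM, and of 11 endothelial and adipocyte markers 4 were, with CDH5 at up to 1.01. Of 14 neuronal genes 6 were, with UCHL1 at up to 62.27 RPKM, of 20 germline and cancer-testis genes 8 were, with MAGEA4 at up to 102.54, and of 22 homologous recombination genes 17 were. Of these 17, 7 reached 1 RPKM in a library, and low values of long genes reflect the gene span as well as expression.

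Over the 4 lines at day 5, the mean drug effect passed for 3526 of 4721 genes, 1718 higher and 1808 lower. AGRN fell by 1.54 ± 0.027 on the log2 scale, IFI6 by 1.61 ± 0.035, the transporter gene MFSD3 by 1.31 ± 0.048 and GPAA1, which acts in GPI anchor attachment, by 1.12 ± 0.023. PRPF38B rose by 0.88 ± 0.02, CREBZF by 0.69 ± 0.012, SNHG1 by 0.72 ± 0.024 and the AP-1 gene FOSL1 by 0.67 ± 0.028, each with an adjusted p under 0.05 by limma. By list, 8 of 8 interferon-stimulated genes fell (median -0.703) and 8 of 8 antigen presentation genes fell (median -0.48). Of the ribosomal protein genes 31 of 33 fell and 1 rose (median -0.206). Mitochondrially encoded genes rose in 12 of 13 cases (median 0.286), and ATF4 targets rose in 9 of 11 cases and fell in 1 (median 0.253), these lists all with the same counts adjusted over the list alone. Ribosome biogenesis genes rose in 12 of 15 cases and fell in 3, the same adjusted over the list alone (median 0.154). With an estimated correlation the adjusted p of these 6 lists ran from 0.279 to 0.694. The fit on recovered reads called 7731 of 10725 genes.

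Genes past the threshold in 4 of 4 lines at day 5 with the same direction were 485, of which 139 rose and 346 fell, against 13.3 and 27.6 if the lines were independent. Over 6 of 6 comparisons 63 genes rose and 193 fell, with AGRN, IFI6, ACADVL, NAPRT and GPAA1 among those that fell and PRPF38B among those that rose. Across genes, the drug effects of a pair of comparisons had a Pearson r of 0.373 to 0.66 and a Spearman rho of 0.338 to 0.73, and genes are not independent replicates. Without EPZ015666 replicate A of MDAMB436 the 485 genes became 316, and with the fit on recovered reads they became 1177.

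The drug effect differed between the lines at day 5 for 3761 of 4721 genes by limma's F test. CYR61, a YAP target, had effects of 1.4 in COV362, -0.49 in OVCAR8, -0.3 in MDAMB436 and 0.08 in BT549 on the log2 scale (F = 753, adjusted p = 3.29e-09). INSIG1, which holds back cholesterol synthesis, had effects of -1.04 in COV362, -0.19 in OVCAR8, 0.15 in BT549 and 0.54 in MDAMB436 (F = 430). PSAT1 rose by 0.92 in OVCAR8 against -0.44 in COV362 (F = 410). CD24 fell by 1.43 in BT549 and 1.1 in OVCAR8 against 0.07 in COV362 and 0.04 in MDAMB436 (F = 256). Comparing the breast lines with the ovarian lines, 2054 genes differed, 916 with a more positive effect in the breast lines and 1138 with a more negative one. Other pairings of the same lines gave more genes, 2573 and 2464. Cholesterol genes had the more positive effect in the breast lines in 15 of 17 cases (median difference 0.294, adjusted p = 6.67e-08). ATF4 targets had the more negative effect there in 11 of 11 cases (median difference -0.413, adjusted p = 1.24e-07), with the same counts for both adjusted over the list alone. With an estimated correlation their adjusted p was 0.308 and 0.279. The cholesterol list did not part the tissues line by line, since its median of 0.251 in the ovarian line OVCAR8 lay between 0.169 in BT549 and 0.36 in MDAMB436, with -0.286 in COV362. At day 3 the effect in BT549 differed from that in OVCAR8 for 120 of 5370 genes, 74 more positive and 46 more negative in BT549. Those 120 genes became 59 without BT549 EPZ015666 day 3 replicate A, 36 without replicate B, 18 without OVCAR8 DMSO day 3 replicate B, 16 and 21 without OVCAR8 EPZ015666 day 3 replicate A and B, and 0 by limma without OVCAR8 DMSO day 3 replicate A (685 at an unadjusted p under 0.05). With the replicate letter as a term 60 genes were called, and the fit on recovered reads of all libraries called 817 at day 3. That fit also called 8251 genes between the lines and 4373 between the tissues.

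The drug effect at day 5 differed from that at day 3 for 373 of 6249 genes in BT549, 95 more positive and 278 more negative at day 5. CD24 had a difference of -1.09 ± 0.085 (adjusted p = 0.00619), and the collagen gene COL3A1 and the chaperone gene CLU one of -0.84 each. Extracellular matrix and mesenchymal genes were more negative at day 5 in 7 of 20 cases (12 more negative and 1 more positive adjusted over the list alone, median difference -0.253, adjusted p = 8.7e-05, and 0.406 with an estimated correlation). Mitosis genes were more positive in 2 of 28 cases (9 adjusted over the list alone, median difference 0.157, adjusted p = 1.24e-07, and 0.5 with an estimated correlation). Leaving out DMSO day 5 replicate A, DMSO day 5 replicate B, EPZ015666 day 5 replicate B, DMSO day 3 replicate A, EPZ015666 day 3 replicate A and EPZ015666 day 3 replicate B gave 18, 22, 38, 106, 195 and 136 genes. Leaving out DMSO day 3 replicate B gave 609, and leaving out EPZ015666 day 5 replicate A gave 0 by limma (1005 at an unadjusted p under 0.05). The replicate letter as a term left 91 genes, the fit on recovered reads called 1243 and a fit with no filter on low values called 113.

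In OVCAR8 the drug effect differed between the days for 472 of 6328 genes, and for 5 with the replicate letter as a term. Of these 146 (30.9%) were more positive and 326 more negative at day 5, against 248 (57.4%) and 184 after median-of-ratios scaling. CEBPD, an acute-phase transcription factor gene, had a difference of -0.73 ± 0.071 (adjusted p = 0.0257), the cell cycle inhibitor gene CDKN1C one of -0.72 and the scaffold gene AHNAK one of 0.55. Ribosomal protein genes were more negative at day 5 in 14 of 33 cases (25 more negative and 1 more positive adjusted over the list alone, median difference -0.242, adjusted p = 6.68e-07, and 0.638 with an estimated correlation). Without DMSO day 5 replicate A, DMSO day 5 replicate B, EPZ015666 day 5 replicate A, EPZ015666 day 5 replicate B, DMSO day 3 replicate B or EPZ015666 day 3 replicate A, limma called 0 genes (1560, 1949, 1540, 1620, 1440 and 1804 at an unadjusted p under 0.05). It called 3 without DMSO day 3 replicate A and 6 without EPZ015666 day 3 replicate B. The fit on recovered reads called 1959 genes and a fit with no filter on low values called 149.

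Under DMSO alone, day 5 differed from day 3 for 1044 genes in BT549 (668 higher and 376 lower at day 5) and 2322 in OVCAR8 (1313 higher and 1009 lower). TXNIP, a glucose-responsive gene, was higher at day 5 by 0.87 ± 0.081 in BT549 and by 1.53 ± 0.075 in OVCAR8 on the log2 scale (adjusted p = 0.00241 and 0.000442). CCND1 was lower at day 5 in OVCAR8 by 0.98 ± 0.044, and SOCS3 was higher there by 0.98 ± 0.054. DNA replication genes were lower at day 5 in 12 of 24 cases in BT549 (13 adjusted over the list alone, median difference -0.206) and 14 of 26 in OVCAR8 (16 adjusted over the list alone, median difference -0.143), with adjusted p = 1.24e-07 and 1.04e-05, and 0.404 and 0.448 with an estimated correlation. Antigen presentation genes were higher at day 5 in 9 of 10 cases in OVCAR8 (10 adjusted over the list alone, median difference 0.438, adjusted p = 3.1e-05, and 0.336 with an estimated correlation). In BT549 the 1044 genes became 165 without DMSO day 5 replicate A, 158 without DMSO day 5 replicate B, 622 and 621 without EPZ015666 day 5 replicate A and B, 621 without DMSO day 3 replicate A, and 2440 in the fit on recovered reads. In OVCAR8 the 2322 genes became 1449 without DMSO day 5 replicate A, 1173 and 1209 without DMSO day 3 replicate A and B, and 4626 in the fit on recovered reads.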

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

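The tests of a lag behind the vehicle, of poly(A) selection and of S phase were chosen only after the result was seen, as were the split test of the differences between all lines, the GC and span correction and the fit on recovered reads. The results on days, lines and tissues were singled out because the drug effect of a gene, a list or a count differed by limma's or camera's test of the difference itself. The interferon and antigen presentation, GC and histone patterns were instead picked from the drug comparisons after their values had been seen. The lists among them also passed with fry and in the fit on recovered reads, which was required after the first values had been seen.

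Between the days, 373 genes differed in BT549. The log2 differences, day 5 effect minus day 3 effect, were -1.09 for CD24, 1.09 for FAM27B, -0.87 for the complement gene CFD, -0.84 for CLU, -0.84 for COL3A1, -0.8 for SEPT2P1, -0.78 for the tubulin gene TUBA1A and -0.74 for S100A6. FAM27B and SEPT2P1 have close copies, so the source of their reads is uncertain. The list medians were 0.114 for DNA replication, 0.157 for mitosis, 0.115 for the ATR-CHK1 checkpoint, 0.173 for ribosome biogenesis, 0.24 for heat shock genes, -0.178 for antigen presentation, -0.21 for the unfolded protein response and -0.253 for extracellular matrix and mesenchymal genes. With an estimated correlation none of these lists passed (adjusted p = 0.336 to 0.531).

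In OVCAR8 472 genes differed between the days. The differences were -0.73 for CEBPD, -0.72 for CDKN1C, -0.64 for NAPRT, -0.59 for the laminin receptor gene BCAM, -0.57 for ID1, -0.57 for SOCS3, -0.55 for the pseudogene RPS24P8 and 0.55 for AHNAK. The list medians were -0.121 for Sm proteins and snRNP assembly, -0.109 for DNA replication, 0.102 for ATF4 targets, 0.13 for the unfolded protein response and -0.242 for ribosomal proteins, and with an estimated correlation their adjusted p ran from 0.336 to 0.694. With the replicate letter as a term 91 genes differed in BT549 and 5 in OVCAR8. Leaving out 1 library lowered the counts of both lines, to 18, 22, 38, 106, 195 and 136 genes in BT549 without DMSO day 5 replicate A, DMSO day 5 replicate B, EPZ015666 day 5 replicate B, DMSO day 3 replicate A, EPZ015666 day 3 replicate A and EPZ015666 day 3 replicate B, and to 6 without EPZ015666 day 3 replicate B and 3 without DMSO day 3 replicate A in OVCAR8. Limma called 0 genes in BT549 without EPZ015666 day 5 replicate A (1005 at an unadjusted p under 0.05) and 0 in OVCAR8 without any of the other 6 libraries (1440 to 1949 unadjusted), while BT549 without DMSO day 3 replicate B had 609 and the fit on recovered reads of all libraries called 1243 and 1959.

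Between BT549 and OVCAR8 at day 3, 120 genes differed. The differences, BT549 minus OVCAR8, were 1.33 for MSLN, 1.12 for the polyamine enzyme gene SAT1, -1.03 for IFI6, -1.03 for BST2, 0.99 for PTGES3P3, -0.81 for CTGF, 0.81 for ACADVL and 0.78 for DKK1. PTGES3P3 is a processed copy of PTGES3. The list medians were -0.141 for DNA replication, -0.317 for ATF4 targets and 0.141 for the unfolded protein response, and their adjusted p with an estimated correlation was 0.404, 0.455 and 0.404. The count of 120 became 59 without BT549 EPZ015666 day 3 replicate A, 36 without replicate B, 18 without OVCAR8 DMSO day 3 replicate B, 16 and 21 without OVCAR8 EPZ015666 day 3 replicate A and B, and 0 by limma without OVCAR8 DMSO day 3 replicate A (685 at an unadjusted p under 0.05), with 60 when the replicate letter is a term and 817 in the fit on recovered reads of all libraries.

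Breast and ovarian lines differed at day 5 for 2054 genes. The differences, breast minus ovarian, were -1.3 for CTGF, 0.96 for INSIG1, -0.91 for LAMA5, 0.82 for ISG15, 0.77 for SKA2P1, 0.73 for the sterol enzyme gene MSMO1, 0.71 for HES1 and -0.7 for STC2. The list medians were 0.0749 for mitosis, 0.28 for interferon-stimulated genes, -0.413 for ATF4 targets, -0.199 for the unfolded protein response, 0.294 for cholesterol genes, -0.241 for hypoxia and glycolysis, -0.302 for immediate early genes and 0.151 for ribosomal proteins. These lists had an adjusted p of 0.279 to 0.638 with an estimated correlation. In the drug comparisons OVCAR8 had cholesterol and interferon medians of 0.251 and -0.306, nearer to the breast lines (0.169 and 0.36, and -0.592 and -0.318) than to COV362 (-0.286 and -1.2). The 4 lines allow 3 pairings, and breast against ovarian gave the fewest genes, 2054 against 2573 and 2464. The outcome named in advance for chance, another pairing with as many genes, was met. The 2054 genes therefore cannot be read as a difference between tissues rather than between lines. With 3 pairings a share under 0.05 could not have been reached.

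Between all 4 lines at day 5, 3761 genes differed. The largest F values were 753 for CYR61, 430 for INSIG1, 410 for PSAT1, 341 for the desaturase gene SCD, 335 for the stress gene PPP1R15A, 281 for CTGF, 256 for CD24 and 248 for the ribosomal RNA methyltransferase gene FTSJ3. The drug libraries, and the vehicle libraries, were reassigned between the lines in 100 splits, with line means and the mean drug effect kept. Of these, 1 gave as many genes, the real one, and the highest other gave 391. This argues against chance in how the libraries fall, without excluding it. For the effect common to the lines, drug and vehicle were split within lines. The real split gave 3526 genes, the only 1 of 100 with as many. The highest other split gave 2505, and this too argues against such chance without excluding it. That other split keeps drug and vehicle libraries apart in 3 of 4 lines. Neither test covers chance between cultures if A and B came from a single culture.

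The fall of interferon-stimulated and antigen presentation genes in 6 of 6 comparisons may be an effect of the drug. Antigen presentation genes rose with time under DMSO, so drug cultures that lag behind the vehicle are a candidate explanation. Interferon-stimulated genes at day 5 of EPZ015666 were also below DMSO of day 3 (median -0.175, the higher of BT549 and OVCAR8, with fry adjusted p = 0.000189 and 0.00166). In BT549 and OVCAR8 this argues against a lag no longer than the time from day 3 to day 5 as their whole cause. A longer lag was not tested, and COV362 and MDAMB436 had no day 3 libraries. However, in OVCAR8 6 of 10 genes were lower and 1 higher, and camera did not pass (adjusted p = 0.108, and 0.576 with an estimated correlation). In BT549 camera passed (4.44e-05) but not with an estimated correlation (0.187). Antigen presentation genes were at -0.254 in BT549, where 7 of 10 were lower and 0 higher by limma (fry adjusted p = 0.00217, camera 0.000632, and 0.502 with an estimated correlation). This argues against a lag of that length as the whole cause there. In OVCAR8 they were at 0.018, with 2 of 10 lower and 2 higher, so in that line a lag and a direct effect cannot be told apart. After the GC and span correction 6 of 6 comparisons kept a lower interferon list and 6 of 6 a lower antigen presentation list (highest adjusted p 0.0104 and 0.0175). Their medians were at 82.4% to 117% and 65.6% to 104.5% of those before it, the lowest from -0.489 to -0.321 for antigen presentation in OVCAR8 at day 5. This argues against these trends as the whole cause, although not against a part. The calls do not hold with an estimated correlation (adjusted p = 0.343 to 0.528), and reads shared between HLA genes were not tested.

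Of the genes changed in 6 of 6 comparisons, the 193 lower ones had a median GC content of 59% and the 63 higher ones of 46%. GC content was that of the longest transcript of each gene. Gene span, introns included, in place of GC content is argued against, since at least 94.2% of the GC slope was kept with a span term. Transcript length was not used as a term, so it is not covered. The slopes of the drug effect ran from -0.0283 to -0.102 log2 per 10% of GC. Of the 6, 2 exceeded the largest slope between replicates, 0.0952 in size. That largest slope was between the DMSO libraries of BT549 at day 3. The drug slope there, -0.0452, was smaller in size than each slope between its own replicates (DMSO -0.0952, EPZ015666 0.06). In BT549 at day 3 a GC bias that varies from library to library and a drug effect on GC-rich genes therefore cannot be told apart. The drug slope was larger than each in BT549 and OVCAR8 at day 5 (-0.102 against -0.0296 and -0.000152, and -0.0985 against -0.0191 and -0.00972). It was also larger in OVCAR8 at day 3 (-0.0583 against 7.38e-05 and 0.0315), MDAMB436 (-0.0846 against 0.0552 and -0.00664) and COV362 (-0.0283 against 0.0098 and 0.0156). In these comparisons the values argue against such a bias as the whole cause. They do not exclude it, since each group held 2 libraries. The slopes had the same sign in the 6 comparisons.

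The rise of histone genes in BT549 at day 3, OVCAR8 at day 5 and MDAMB436 could come from weaker poly(A) selection, since most histone transcripts lack a poly(A) tail. Camera called these 3 comparisons. The fit on recovered reads gave histone medians of 0.501 in BT549 at day 5, 0.631 in OVCAR8 at day 3 and 0.0259 in COV362. In these, 7, 6 and 4 of 11 genes rose and 1, 1 and 3 fell. With an estimated correlation the 3 calls do not hold (adjusted p = 0.518, 0.714 and 0.562). The calls in OVCAR8 and MDAMB436 also ended with median-of-ratios scaling (0.0874 and 0.0553) and the GC and span correction (0.0536 and 0.116), at medians of 0.804 and 0.645, and 0.908 and 0.719. At most 1 small RNA of the 5 needed was measured at the minimum level in these comparisons, too few for a test. The 1 measured changed by 1.21 log2 in BT549 at day 3, past the threshold, and by 1.22 in OVCAR8 at day 5, not past it. In the other comparisons of these lines it changed by 1.18 in BT549 at day 5, past the threshold. In OVCAR8 at day 3, where the histone median was also above 0, it changed by -1.48, not past the threshold. The U6 genes named above also rose in OVCAR8 at day 5 and MDAMB436, although the source of their reads is uncertain. The ribosomal RNA locus took 1.39% and 0.27% of the reads in drug replicates A and B of BT549 at day 3. It took 0.23% and 4.54% in OVCAR8 at day 5 and 0.28% and 0.32% in MDAMB436, so not high in both replicates. Weaker selection and a rise of polyadenylated histone transcripts therefore cannot be told apart. More cells in S phase should raise the DNA replication list, but it had a median of -0.0836 or below in the 3 comparisons. There 8, 10 and 10 of its genes fell and 1, 4 and 3 rose (fry adjusted p = 0.0189, 0.0131 and 0.0439). By camera the list passed in BT549 at day 3 alone, and not with an estimated correlation. In OVCAR8 at day 5 the median of all genes was itself -0.0426. The values argue against more cells in S phase, but the share of cells in S phase was not measured. H1F0, which is polyadenylated, fell in each of the 3 comparisons.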

How the results depend on the processing

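The fit on recovered reads (limma-voom), the GC and span correction and the alternatives for the DMSO comparisons, the overlap and the list tests other than camera's estimated correlation, fry and the replicate block were chosen only after the result was seen. Of the named gene results, the pseudocount of 0.1 left 1053 of 1061 on the same side of the threshold with the same direction, median-of-ratios scaling 1035 of 1061, the replicate block 1001 of 1061, the fit on recovered reads 1005 of 1056 and leaving out a library 8570 of 9284. Leaving out a library ended 639 calls and turned 0 by limma. A single result reversed, TIMELESS in breast against ovarian lines. It was at -0.1181 (adjusted p = 0.0389) in the fit on recovered reads against 0.04 ± 0.026 (adjusted p = 0.22) by limma. Adding 1 to RPKM before the log shrinks changes at low RPKM. In BT549 at day 5 TIMELESS went from 2.48 to 1.25 RPKM, a log2 change of -0.63 against -0.98 in that fit. Lines with unlike levels are shrunk unequally, which can affect contrasts between lines and tissues. Whether it made this reversal was not tested.

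A mean RPKM of at least 5 tested fewer genes and gave 1102 (BT549 day 5), 516 (BT549 day 3), 1490 (OVCAR8 day 5), 973 (OVCAR8 day 3), 1824 (COV362) and 1172 (MDAMB436) genes. It gave 231 for the days in BT549, 590 and 1022 for DMSO over time in BT549 and OVCAR8, 1182 for the common effect, 1291 between lines, 712 between tissues, 46 for BT549 against OVCAR8 at day 3, 187 in 4 of 4 lines and 91 in 6 of 6 comparisons. No filter on low values tested more genes and gave 5730 (OVCAR8 day 5), 7266 (COV362), 113 and 149 for the days in BT549 and OVCAR8, 9541 for the common effect, 9808 between lines, 5430 between tissues and 559 at day 3.

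The fit on recovered reads tested more genes and gave 5021 and 3021 (BT549 day 5 and day 3), 6952 and 4817 (OVCAR8 day 5 and day 3), 8810 (COV362) and 5826 (MDAMB436). It gave 1243 and 1959 for the days in BT549 and OVCAR8, 2440 and 4626 for DMSO over time, 7731 for the common effect, 8251 between lines, 4373 between tissues, 817 at day 3, 1177 in 4 of 4 lines and 612 in 6 of 6 comparisons.

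For BT549 at day 3, 1 fit over all 24 libraries gave 2487 genes, the 4 libraries alone 548 and the GC and span correction 2026, and the 4 libraries alone gave 160 genes in 6 of 6 comparisons; the cause was not tested. The replicate block gave 91 and 5 genes for the days in BT549 and OVCAR8 and 60 at day 3. The plan fixed in advance did not use the letters as pairs. The A minus B differences of drug and vehicle had correlations across genes from -0.196 in BT549 at day 3 to 0.214 in COV362, so some pairing in COV362 cannot be excluded. Of the 170 list tests, camera with an estimated correlation called 0 (14 at an unadjusted p under 0.05) and fry called 99.

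Leaving out each library in turn gave 1381 to 2800 genes in BT549 at day 5, 615 to 1125 at day 3, 1383 to 2236 in OVCAR8 at day 3 and 1323 to 2385 in MDAMB436. It gave 0 to 609 for the days in BT549, 0 to 6 in OVCAR8, 158 to 1120 and 1173 to 2310 for DMSO over time, 0 to 132 at day 3 between lines (limma, with 1005, 1440 to 1949 and 685 at an unadjusted p under 0.05 for the counts of 0) and 316 to 505 in 4 of 4 lines. The counts stayed within 1.5 times in OVCAR8 at day 5 (2707 to 3581), COV362 (3728 to 4056), the common effect (3392 to 3489), between lines (3536 to 3740), between tissues (1799 to 2013) and for 6 of 6 comparisons (180 to 261). A group left with 1 library was assumed to vary like the others. The median gene varied 1.86 to 5.09 times as much between replicates, in chi-square, as counting error gives, so depth sets a part of the spread.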

Other observations

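The comparison of COV362 with the other 3 lines was chosen only after the result was seen, as were the genes of the next paragraph among the list members.

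TIMELESS fell in each of the 6 drug comparisons, to 0.419-fold in BT549 at day 3, 0.506-fold at day 5, 0.76-fold and 0.659-fold in OVCAR8 at day 3 and day 5, 0.568-fold in COV362 and 0.628-fold in MDAMB436. H1F0 fell as well, to 0.524-fold and 0.413-fold in BT549 at day 3 and day 5, 0.688-fold and 0.692-fold in OVCAR8, 0.741-fold in COV362 and 0.721-fold in MDAMB436. The mitotic kinesin gene KIF20A fell to 0.66-fold and 0.631-fold in OVCAR8, 0.776-fold in COV362, 0.659-fold in MDAMB436 and 0.818-fold in BT549 at day 3, but not in BT549 at day 5 (log2 change 0.02). FDXR, a mitochondrial reductase gene and p53 target, fell to 0.442-fold in BT549 and 0.478-fold in OVCAR8 at day 5. The chaperone gene HSPH1 rose 1.62-fold in BT549 and 1.66-fold in OVCAR8 at day 5 and 1.44-fold in COV362, and EDEM1, which sends misfolded glycoproteins to degradation, rose 1.98-fold in OVCAR8 at day 5 and 1.42-fold in MDAMB436.

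In COV362 against the other 3 lines at day 5, the drug effect differed for 2768 genes, 1835 more positive and 933 more negative in COV362. Cholesterol genes were more negative in COV362 in 16 of 17 cases (median difference -0.645, adjusted p = 3.97e-13) and interferon-stimulated genes in 8 of 8 (median difference -0.593, adjusted p = 1.29e-06), each with an adjusted p of 0.0504 with an estimated correlation. The unfolded protein response was more positive in 13 of 15 cases and more negative in 1 (median difference 0.459, adjusted p = 0.000429, and 0.107 with an estimated correlation). Hypoxia and glycolysis genes were more positive in 7 of 8 cases (median difference 0.379, adjusted p = 0.0033, and 0.148 with an estimated correlation). The contrast was picked because of these lists, so its p-values are not independent evidence.

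The 4 genes of the ribosomal RNA locus took over 1% of the reads in 2 libraries, OVCAR8 EPZ015666 day 5 replicate B (4.54%) and BT549 EPZ015666 day 3 replicate A (1.39%), against 0.23% in the lowest library. Without the former, OVCAR8 at day 5 had 2802 genes past the threshold, and without the latter BT549 at day 3 had 1068.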
